A study of Mus musculus with 14 samples.

How the data were processed

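Small RNA libraries from mouse dorsal root ganglia (DRG, the ganglia that hold the cell bodies of sensory neurons) were compared between the strains C57BL/6 and CAST/Ei, from naive animals and from animals whose sciatic nerve had been crushed. There were 14 libraries: 5 C57BL/6 naive, 3 C57BL/6 injured, 3 CAST/Ei naive and 3 CAST/Ei injured. The series' design text calls the libraries of a group biological replicates. Per the labels' protocols, ganglia were dissociated after removal, the miRVana kit gave the RNA and the Ion Total RNA-Seq kit the libraries. Per the same protocols, injured animals were males of 8 to 10 weeks whose left sciatic nerve was crushed for 30 s. No age is recorded for the naive animals, and the sex stated is that of the injured ones, so matching on either could not be checked. The time between injury and dissection, the ganglia taken, the genome build, the release of miRNA names and any sequencing batch are not given in the sources used here.

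Bowtie2 was used for alignment, per the submitters' processing notes, with no version given. The deposited files hold 1 signal value for each of 1123 mature miRNAs in each library, which their names call CPM (counts scaled to a common library total). The scaled values total between 867581 and 1311857 per library, so they are not plain CPM. In every library 100% of the values are whole multiples of the value of 1 read, within a tolerance of 1e-06 reads. Whole reads were therefore recovered, and TMM factors computed from these reads with edgeR equal the reciprocals of the scaled totals to within 9.1e-06. The deposited signal is thus CPM on TMM-scaled library sizes and is called CPM throughout. C57BL/6 injured library 1 has the least certain recovery, because its read step lies close to a round decimal, so edgeR was also run without that library.

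The recovered reads total 6873535, 11608088, 4007706, 11422051 and 5770191 in C57BL/6 naive libraries 1 to 5. They total 9967246, 8999600 and 10276880 in the C57BL/6 injured libraries, 15642360, 8731243 and 6653095 in the CAST/Ei naive libraries, and 9945200, 5401274 and 13629728 in the CAST/Ei injured libraries. One read is worth 0.0674 to 0.253 CPM. A library's floor, taken as 3 reads, lies between 0.202 and 0.760 CPM, and over whole groups the floor is 0.0798 CPM in C57BL/6 naive, 0.0975 in C57BL/6 injured, 0.105 in CAST/Ei naive and 0.0937 in CAST/Ei injured. The libraries carry no molecular identifiers, so floors and the 95% intervals of read ratios cover counting error only.

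Values were tested as log2(CPM + 1). The 638 miRNAs with at least 5 CPM in at least 3 libraries were kept, and 1 model with a mean for each of the 4 groups was fitted over all 14 libraries with limma-trend (R 4.3.3, limma 3.58.1). It gave 6 contrasts. They were the injury effect in each strain, the strain effect (CAST/Ei minus C57BL/6) in naive and in injured DRG, the difference between the strains' injury effects (the interaction), and the injury effect averaged over strains. P-values are two-sided and adjusted by Benjamini and Hochberg within each contrast over the 638 miRNAs, with a threshold of 0.05. Counts at unadjusted p under 0.05 include those that chance alone gives, a share of about 0.05 of the miRNAs tested. Fold changes are on the log2(CPM + 1) scale, which understates the change of miRNAs at a few CPM. Levels are means of CPM with the standard deviation (SD), and log2 fold changes carry their standard error (SE). The plan had assumed plain CPM, and the same limma test was kept for the scaled values.

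For each contrast the text names, among miRNAs past the threshold whose groups do not overlap, the 10 with the largest increases and the 10 with the largest decreases. For the interaction and the averaged effect only the threshold applies. Where fewer than 5 passed, the 5 with the lowest p are named as not passing. Up to 4 kept members of each described list, the 10 most abundant miRNAs, miR-21a, the miR-183 cluster and miR-124 are also named. The tests, the naming rule, the lists and most alternative settings were fixed before the data were examined. Any other miRNA named was chosen after its values were seen and is marked so.

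Lists of miRNAs came from general knowledge, without papers at hand. They were miRNAs reported up and reported down after nerve injury, neuronal, myelinating glia, leukocyte, erythrocyte, skeletal muscle, endothelial, mural cell, fibroblast, epithelial and hepatocyte miRNAs, the miR-17 and paralogous clusters, and the let-7, miR-29, miR-30 and miR-34 families. The others were the miR-183, miR-132, Dlk1-Dio3, Sfmbt2 and X-linked testis clusters, the Hox cluster miRNAs and the hypoxia miRNA miR-210. The Dlk1-Dio3 list is not complete, since it does not hold miR-341, which lies in the same domain. Counts and tests of that cluster cover the listed members only. Lists with at least 3 kept members (22 of 24) were tested with camera from limma at a preset correlation of 0.01, adjusted within each contrast, and again with an estimated correlation and with fry. Hairpin positions and host genes come from GENCODE vM21 (GRCm38), in which 1097 of the 1123 names matched a gene. Members of the Sfmbt2 cluster, miR-344d and miR-344h, miR-133a, miR-218, miR-486 with miR-3107, and miR-126a with miR-126b are made from near-identical copies, and the authors' counting may have split their reads, so their values are uncertain. Sequence differences between CAST/Ei and the C57BL/6 reference in the mature miRNAs were not analysed here.

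The alternative settings were pseudocounts of 0.5 and 5, no filter, a filter of 50 CPM, quantile normalization, median-of-ratios scaling, totals without the 3 most abundant miRNAs, array quality weights, models of only the groups compared, edgeR's quasi-likelihood test (4.0.16) and DESeq2 (1.42.0) on the recovered reads, the replicate number as a block, and each replicate left out in turn. Runs without C57BL/6 naive libraries 4 and 5, and edgeR without C57BL/6 injured library 1, were added after seeing the data. Correlations between contrasts were set against 2000 simulations of unchanged groups, which drew each miRNA independently. Real miRNAs move together, so the simulated ranges are too narrow. The simulations also gave all groups a common spread for each miRNA. The main procedure was tested on simulated reads drawn from the real means and library sizes. It recovered 97.0% of 4-fold and 36.4% of 2-fold changes for the C57BL/6 injury effect (635 miRNAs tested), 89.4% and 19.7% for CAST/Ei injury (638) and 98.5% and 36.5% for strain in naive DRG (622). The corresponding shares were 87.7% and 21.0% for strain in injured DRG (636), 55.4% and 0% for the interaction (633), and 100% and 65.6% for the averaged injury effect (626). These shares probably overstate the power of the real tests. Far more miRNAs were changed than the real contrasts called, which makes the adjusted threshold easier to pass. The simulated runs made 101 calls against 20 for C57BL/6 injury and 76 against 7 for CAST/Ei injury. They also drew each miRNA independently and held no libraries that stood apart. The main model has no block. Replicate numbers were taken to pair the libraries of a comparison where the deviations from the group means correlated above 0.1 in every same-numbered pair. Among the comparisons of 2 groups this held, narrowly, for strain in naive DRG alone, in 3 of 3 pairs (0.104 to 0.114). The labels name no shared litter, batch or day, and the check was made for each comparison only after the counts of calls had been seen. No deposited library was left out of the main model, and no pair of libraries compared was a duplicate, with chi-square per degree of freedom from 51.6 to 5239 over 19 pairs.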

Results

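Mature miRNAs were sequenced from the DRG of 2 inbred mouse strains, C57BL/6 (5 naive and 3 injured libraries) and CAST/Ei (3 naive and 3 injured), with injury by crush of the sciatic nerve. The comparisons ask which miRNAs respond to the injury in each strain, whether the response differs between the strains, and which miRNAs differ between the strains with and without injury. The libraries hold 4007706 to 15642360 reads, and 949 to 1084 of the 1123 miRNAs were detected in each.

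The neuronal miRNA miR-138-5p was the most abundant, with a mean of 80782 CPM over the 14 libraries, or 8.00% of the total. It was followed by miR-125b-5p at 60133 CPM, miR-29b-3p at 53285, miR-23b-3p at 38799, miR-26a-5p at 37339 and miR-218-5p at 30808. miR-338-3p, a miRNA of myelinating glia, stood at 29046 CPM, miR-29a-3p at 28622, miR-24-3p at 27674 and miR-23a-3p at 22272. The neuronal miR-124-3p reached 20397 ± 9428 CPM (SD, n = 5) in C57BL/6 naive, 21254 ± 2474 (n = 3) in C57BL/6 injured, 16907 ± 10560 (n = 3) in CAST/Ei naive and 16089.7 ± 1158 (n = 3) in CAST/Ei injured DRG. It passed in no contrast with limma over all groups, but did for strain in injured DRG when only the groups compared were modelled (adjusted p = 0.0413).

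C57BL/6 naive libraries 4 and 5 stood apart from the other 12. Their Spearman correlations with the others were 0.871 to 0.926, against 0.951 with each other and at least 0.925 among the other 12. The 10 most abundant miRNAs took 56.6% and 50.1% of their reads, against 37.7% to 45.9% elsewhere. miR-218-5p reached 260520 and 81351 CPM in them, against a median of 4956 in the other 12 libraries, and miR-367-3p reached 48100 and 13814 CPM against 526.2. miR-218-5p therefore averaged 71341 ± 110811 CPM (SD, n = 5) in C57BL/6 naive DRG, and 8472, 10957 and 5439 CPM in the C57BL/6 injured, CAST/Ei naive and CAST/Ei injured groups. The shift took in whole lists. Relative to naive libraries 1 to 3, the median epithelial miRNA was 3.25 higher on the log2 scale, the hepatocyte miR-122-5p 5.23 and miR-210 (2 arms) 1.24, while the median of all kept miRNAs differed by −0.06. Fibroblast miRNAs differed by 0.59 and the miR-30 family by 0.53 in the median, and the medians were −1.22 for erythrocyte miRNAs, −0.95 for the miR-132 cluster, −0.87 for myelinating glia miRNAs and −0.63 for the miR-29 family. Smaller medians were −0.31 for endothelial miRNAs, −0.28 for Hox cluster miRNAs, −0.27 for the Sfmbt2 cluster and −0.20 for the Dlk1-Dio3 cluster. Both libraries stayed in the model, and the counts of calls without them stand beside the main ones.

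**Figure D1:**
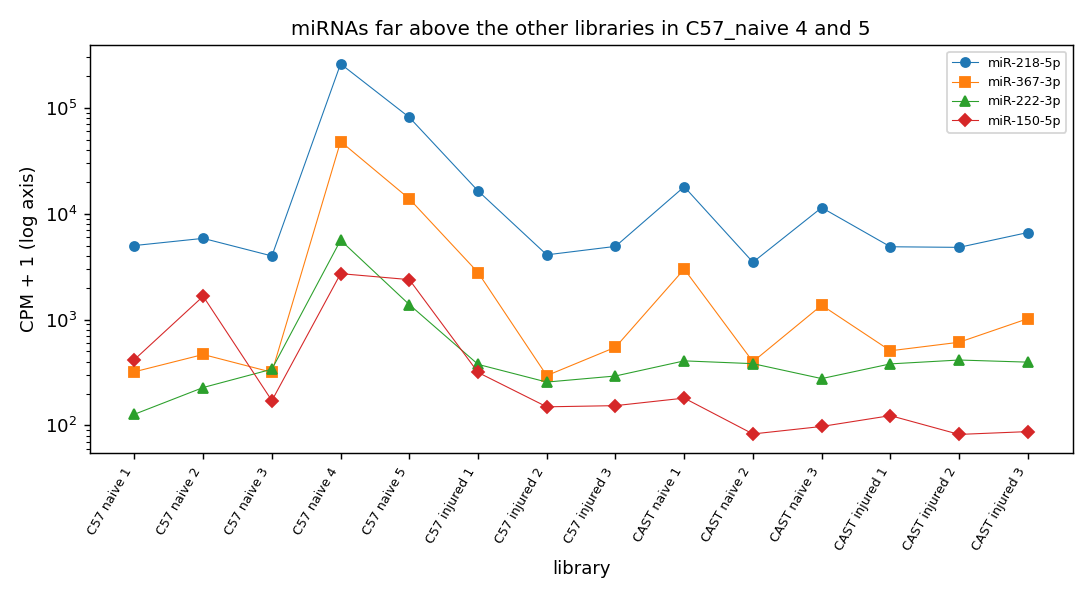
CPM + 1 on a log axis of miR-218-5p, miR-367-3p, miR-222-3p and miR-150-5p in each of the 14 libraries, 1 marker per library joined by a line for each miRNA. In C57BL/6 naive libraries 4 and 5 miR-218-5p stands at 260520 and 81351 CPM, against a median of 4956 in the other 12.

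In C57BL/6 DRG the injury raised miR-21a-5p, a miRNA induced in many damaged tissues, 3.39-fold, from 5722 ± 1957 CPM (SD, n = 5) to 18343 ± 1479 (n = 3). The log2 change was 1.76 ± 0.29 (SE), with a limma adjusted p of 0.00283. miR-6540-5p, which lies on the same strand in an intron of the growth-associated gene Gap43 (chromosome 16, 42303362 to 42303469), rose from 34.8 ± 7.82 to 117 ± 15.6 CPM (log2 1.74 ± 0.24, adjusted p = 0.00101). miR-431-5p, from the Dlk1-Dio3 cluster opposite an exon of Rtl1 (chromosome 12, 109590447 to 109590537), rose from 88.5 ± 15.1 to 285 ± 25.3 CPM (log2 1.69 ± 0.27, adjusted p = 0.00283). miR-511-3p, in an intron of the macrophage gene Mrc1 (chromosome 2, 14261003 to 14261081), rose from 75.1 ± 23.3 to 203 ± 15.6 CPM (log2 1.47 ± 0.26, adjusted p = 0.0054). The skeletal muscle miRNA miR-206-3p fell from 99.2 ± 55.6 to 29.4 ± 4.62 CPM (log2 −1.58 ± 0.36, adjusted p = 0.0215). Over their 28 alternatives miR-6540-5p and miR-431-5p kept adjusted p-values of at most 0.0279 and 0.0258, whereas miR-21a-5p missed the threshold in 1 (range 1.99e-05 to 0.0521), miR-511-3p in 2 (highest 0.104) and miR-206-3p in 5 (highest 0.142).

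The 2 largest log2 increases belonged to scarce miRNAs of the miR-344 group on chromosome 7, which has repeated copies within and beside the non-coding gene A230057D06Rik. miR-344e-3p rose from 0.371 ± 0.785 to 7.94 ± 2.19 CPM (log2 2.82) and miR-344h-3p from 1.38 ± 1.03 to 9.34 ± 3.81 CPM (log2 2.16). The more abundant miR-344d-3p rose from 34.97 ± 14.8 to 90.5 ± 9.89 CPM (log2 1.42). C57BL/6 naive library 3 held most of the naive miR-344e-3p, at 1.77 CPM. miR-7689-3p, in an intron of Sorcs2 on the opposite strand, rose by 1.96, the other arm miR-6540-3p by 1.67 and miR-433-5p by 1.32. The remaining decreases were miR-1224-5p (log2 −1.41), miR-490-3p (−1.35), miR-551b-5p (−1.15) and the muscle miRNA miR-133a-3p, which went from 1753 ± 298 to 858.5 ± 181.9 CPM (−1.03). miR-433-5p, miR-1224-5p, miR-551b-5p and miR-490-3p missed the threshold in 18 of 27, 17 of 28, 15 of 27 and 12 of 27 alternatives. So did miR-133a-3p in 8 of 28 (highest adjusted p 0.197), miR-6540-3p in 5 of 27, miR-344d-3p in 5 of 28, miR-7689-3p in 4 of 27 and miR-344h-3p in 1 of 27. miR-21a-3p had a log2 change of 1.41 ± 0.38 and did not pass (adjusted p = 0.0534), as in 21 of 27 alternatives, while it passed in the others (lowest adjusted p 0.0216).

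**Figure D2:**
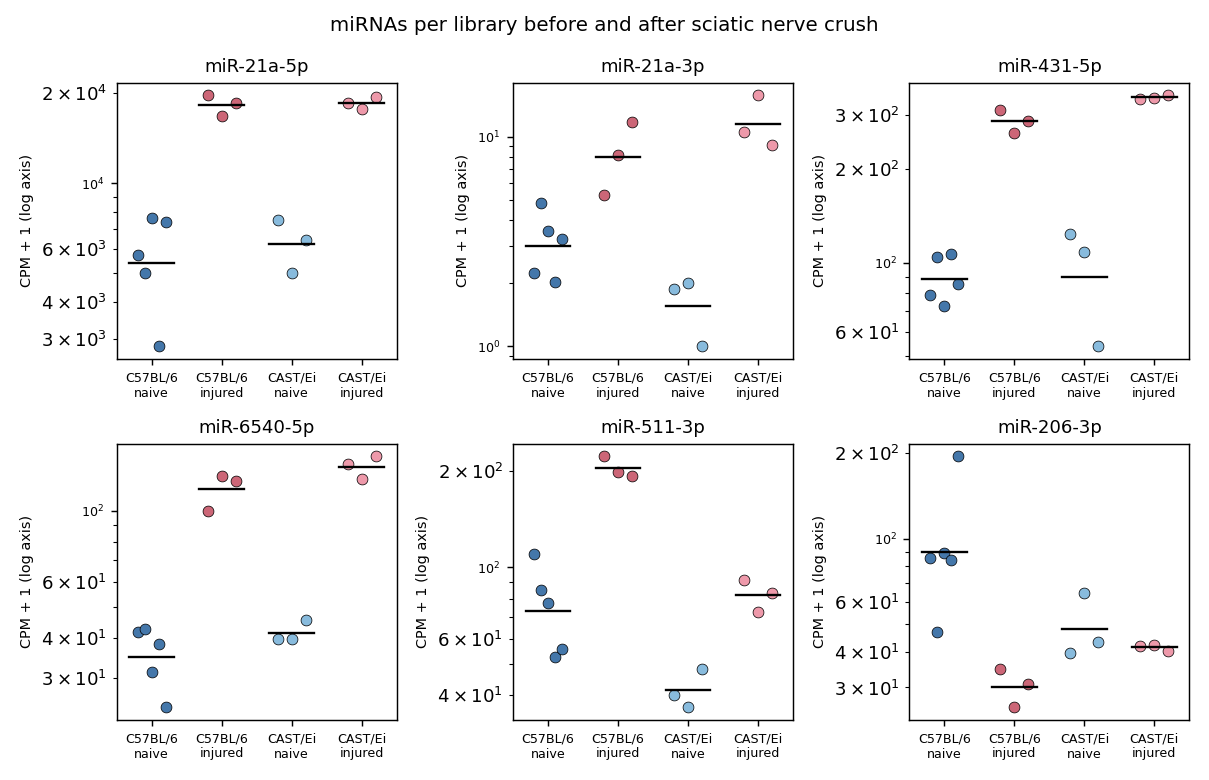
CPM + 1 on a log axis of miR-21a-5p, miR-21a-3p, miR-431-5p, miR-6540-5p, miR-511-3p and miR-206-3p in the 4 groups, with 1 point per library and a line at the mean of log2(CPM + 1). miR-21a-5p lies at 2833 to 7610 CPM in naive C57BL/6 libraries and at 16765 to 19696 in injured ones, and miR-206-3p at 46.1 to 194 and at 24.5 to 33.8.

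Of the 88 kept miRNAs of the Dlk1-Dio3 cluster, an imprinted domain of chromosome 12, 6 rose after injury in C57BL/6 and 0 fell, and 82 did not pass. Adjusted over the list alone, 20 rose and 0 fell. The risers include miR-431-5p, miR-379-5p (log2 1.21), miR-493-5p (1.09) and miR-154-3p (1.04). The cluster's median was 0.47 and 69 of its members were above 0 (camera adjusted p = 1.15e-05, but adjusted p = 0.089 with an estimated correlation). Of 13 miRNAs reported up after nerve injury, 3 rose (miR-21a-5p, miR-431-5p and miR-511-3p) and 0 fell, or 5 and 0 adjusted over the list alone, with a median of 0.66 (camera adjusted p = 0.0105, and adjusted p = 0.089 with an estimated correlation, or 0.0309 when naive libraries 4 and 5 were also left out). Of 10 skeletal muscle miRNAs, 2 fell (miR-206-3p and miR-133a-3p) and 0 rose, or 3 and 0 adjusted over the list alone. The muscle median was −0.63, and it was 0.27 higher in naive libraries 4 and 5 than in naive libraries 1 to 3 (camera adjusted p = 0.00985, and adjusted p = 0.826 with an estimated correlation). Without libraries 4 and 5 the list was called with an estimated correlation too (adjusted p = 0.0309).

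No member of the Sfmbt2 cluster, a set of 47 near-identical repeat-derived miRNAs, passed alone in C57BL/6, with 0 calls also when adjusted over the list alone. Their median was 0.47 and 44 lay above 0, but it was −0.27 in naive libraries 4 and 5 relative to naive libraries 1 to 3 (camera adjusted p = 0.00985, and adjusted p = 0.826 with an estimated correlation). Without those libraries camera no longer called it (adjusted p = 0.0705, range over its 8 alternatives 0.00637 to 0.896). Of 11 leukocyte miRNAs only miR-511-3p rose, or 3 rose and 1 fell adjusted over the list alone. There miR-142-3p (log2 1.63) and miR-142-5p (0.57) count as higher and miR-150-5p (−2.29, or −1.34 without naive libraries 4 and 5) as lower. The leukocyte median was −0.13 and the mean −0.06, while camera pointed upward (adjusted p = 0.882). None of 17 miRNAs reported down after nerve injury passed, also adjusted over the list alone, with a median of −0.06, a mean of 0.02 and camera pointing downward (adjusted p = 0.882). The most changed of them, miR-138-5p and miR-182-5p, had log2 changes of −0.58 and −0.70 (adjusted p = 0.0953 and 0.126).

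The miR-183 cluster, abundant in sensory neurons, passed in no contrast with limma over all 14 libraries. miR-182-5p passed after C57BL/6 injury with DESeq2 (adjusted p = 0.0233) and without C57BL/6 naive library 2 (0.0327), and in the averaged effect likewise (0.0419 and 0.0185). In C57BL/6 miR-182-5p went from 12582 ± 3467 to 7518 ± 763 CPM and miR-183-5p from 11514 ± 5217 to 8462.5 ± 388, and in CAST/Ei from 9095 ± 527 to 6606 ± 744 and from 10009 ± 1015 to 8072 ± 824. None of 24 neuronal miRNAs passed after injury in C57BL/6 (camera adjusted p = 0.727), nor any of 7 myelinating glia miRNAs (adjusted p = 0.882), among which miR-338-3p had a log2 change of 1.31. Among 5 erythrocyte miRNAs none passed, or 1 rose and 2 fell adjusted over the list alone. Those were miR-144-3p (1.66) with miR-486-3p (−1.42) and miR-486-5p (−1.84). Naive libraries 4 and 5 carried much of this, with miR-486-5p at 264 and 205 CPM against 21.8 to 73.9 in libraries 1 to 3 and 18.6 to 26.7 after injury. Without them the changes were 0.94, −0.71 and −0.84. In the miR-132 cluster 0 of 3 passed, or 2 rose adjusted over the list alone, with miR-132-3p at 0.91 (camera adjusted p = 0.238). The cluster's median was −0.945 in naive libraries 4 and 5 relative to naive libraries 1 to 3. In the miR-34 family 0 of 8 passed, or 1 rose adjusted over the list alone. The epithelial list had a median of −1.09 (0 of 6 passed, camera adjusted p = 0.088), and its median was 3.25 higher in naive libraries 4 and 5 than in naive libraries 1 to 3. The endothelial (4 kept members), mural cell (5), fibroblast (8), miR-17 (20), let-7 (22), miR-29 (7), miR-30 (11), Hox (8) and X-linked testis (3) lists also had no member past the threshold. In all, 18 of 22 lists were not called, with camera adjusted p-values of 0.088 to 0.979. The medians of the miRNAs reported down and of the miR-183, neuronal, erythrocyte, mural cell, miR-29 and miR-30 lists changed sign under at least 1 other scaling. The hepatocyte miRNA miR-122-5p (log2 −1.58, adjusted p = 0.427) and the 2 arms of miR-210 (mean −0.86) were too few to test as lists and did not pass.

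In total 20 miRNAs passed the threshold in C57BL/6 (limma), 15 higher and 5 lower, and all 20 had groups that did not overlap. At unadjusted p under 0.05 there were 151. Groups of 95 of the 638 miRNAs (14.9%) did not overlap, where chance gives 3.57%. The increases not named so far were miR-135a-5p (log2 1.24) and miR-323-3p (0.95), a pair singled out after their values were seen. edgeR gave 13 higher and 19 lower and DESeq2 21 and 58, and with the 3 most abundant miRNAs left out of the total the split was 14 and 1. The count rested on single libraries. It was 70 without C57BL/6 naive library 3, and 7, 7 and 6 without C57BL/6 injured library 1, 2 or 3. Without naive libraries 4 and 5 it was 29, of which 18 were among the 20.

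In CAST/Ei DRG 7 miRNAs rose after injury and 0 fell. The largest was the other arm of miR-21a, miR-21a-3p, from 0.623 ± 0.544 CPM (SD, n = 3) to 10.8 ± 3.50 (n = 3), a log2 change of 2.89 ± 0.42 (SE) with an adjusted p of 0.00269. miR-21a-5p rose 2.98-fold, from 6323 ± 1280 to 18568 ± 926 CPM (log2 1.57 ± 0.32, adjusted p = 0.0209). miR-431-5p rose 3.80-fold, from 94.4 ± 36.9 to 340 ± 4.84 CPM, and miR-6540-5p from 40.7 ± 3.36 to 137 ± 11.4 CPM (both adjusted p = 0.00269). miR-7689-3p (log2 2.14 ± 0.45), miR-6540-3p (2.07 ± 0.40) and miR-5114 (1.91 ± 0.39), which lies in an exon of Scd2, were the others. miR-21a-3p, miR-431-5p and miR-6540-5p passed in every alternative that tested them, whereas miR-21a-5p missed the threshold in 6 of 28 (highest adjusted p 0.129), miR-7689-3p in 6 of 27, miR-6540-3p in 4 of 27 and miR-5114 in 7 of 27 (range 0.000137 to 0.318).

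Of the 13 miRNAs reported up after nerve injury, 3 rose in CAST/Ei and 0 fell (miR-21a-3p, miR-431-5p and miR-21a-5p), or 4 and 0 adjusted over the list alone, with a median of 0.59 (camera adjusted p = 4.3e-07, and adjusted p = 0.00285 with an estimated correlation). In the Dlk1-Dio3 cluster 1 of 88 rose, miR-431-5p, and 0 fell, the same counts as adjusted over the list alone. The most changed others, miR-1197-3p (log2 1.56) and miR-154-3p (0.70), did not pass. The cluster's median was 0.11 (camera adjusted p = 1.72e-04, and adjusted p = 0.0739 with an estimated correlation). None of 11 leukocyte miRNAs passed, or 2 rose adjusted over the list alone, with a median of 0.39. miR-511-3p had a log2 change of 0.98, miR-223-5p of 0.94 and miR-142-5p of 0.76 (camera adjusted p = 0.00373, and adjusted p = 0.0739 with an estimated correlation). None of 10 skeletal muscle miRNAs passed, with a median of −0.55 and miR-133a-3p at −0.58 (camera adjusted p = 0.0308, and adjusted p = 0.368 with an estimated correlation). None of 11 members of the miR-30 family passed, with a median of −0.38 (camera adjusted p = 0.0308, and adjusted p = 0.223 with an estimated correlation). The X-linked testis cluster had a median of −0.73 over 3 members, none past the threshold and 1 lower adjusted over the list alone. Its camera adjusted p was 0.0172, with an adjusted p = 0.0739 with an estimated correlation. The other 16 lists had camera adjusted p-values of 0.0968 to 0.666, and the medians of the mural cell, fibroblast, let-7 and Sfmbt2 lists changed sign under at least 1 other scaling.

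The CAST/Ei count of 7 (limma) stood against 41 of 638 miRNAs at unadjusted p under 0.05, where chance alone gives a share of about 0.05. All 7 had groups that did not overlap, as had 170 of the 638 miRNAs (26.6%), where chance gives 10.0%. edgeR called 8, all higher, and DESeq2 14 higher and 2 lower. The count was 3 without CAST/Ei naive library 1, CAST/Ei injured library 1 or CAST/Ei injured library 3, and 4 without CAST/Ei naive library 2 or CAST/Ei injured library 2. Without C57BL/6 naive libraries 4 and 5, which enter through the shared estimate of the spread, it was 17 and held all 7. With the 3 most abundant miRNAs left out of the total, the median log2 change of all miRNAs moved from −0.09 to 0.13.

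The strains shared 5 of the 15 and 7 increases: miR-21a-5p, miR-431-5p, miR-6540-5p, miR-6540-3p and miR-7689-3p. Independent lists of these sizes would share 0.165, but both contrasts use 1 estimate of the spread for each miRNA, which can by itself raise the overlap. Of the 20 C57BL/6 calls 19 had the same sign in CAST/Ei, and 6 of the 7 CAST/Ei calls had the same sign in C57BL/6. The exception, miR-5114, had the lowest p of the interaction, with a difference of 2.04 (95% interval 0.92 to 3.16, adjusted p = 0.529). The difference in injury effect, CAST/Ei minus C57BL/6, was −0.19 (−1.10 to 0.73) for miR-21a-5p, 0.24 (−0.63 to 1.10) for miR-431-5p and −0.01 (−0.79 to 0.76) for miR-6540-5p. For miR-6540-3p it was 0.40 (−0.76 to 1.55) and for miR-7689-3p 0.18 (−1.10 to 1.47). For miR-21a-3p it was 1.48 (0.28 to 2.68, adjusted p = 0.529) and for miR-511-3p −0.49 (−1.33 to 0.36). Across the 638 miRNAs, which are not independent replicates, the injury fold changes of the strains had r = 0.266 and rho = 0.191, with a covariance of 0.0941. The strains share no libraries, and unchanged groups gave r = 0.001 in simulation (95% of values from −0.112 to 0.122). This range is too narrow, because the simulation drew each miRNA independently.

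**Figure D3:**
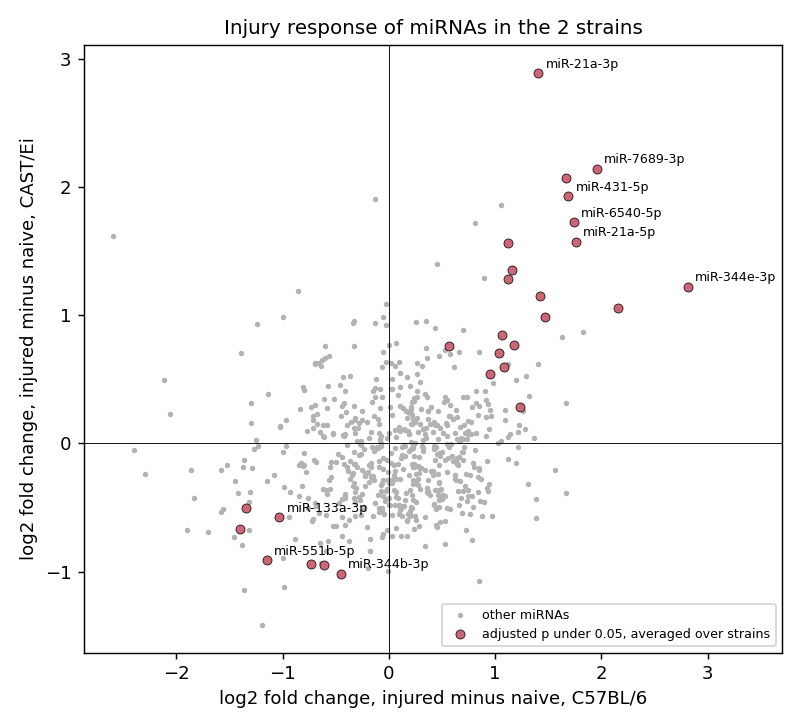
Log2 fold changes of 638 miRNAs after injury (injured minus naive) in C57BL/6 on the x axis and CAST/Ei on the y axis, 1 point per miRNA, with the 27 past the threshold in the average of both strains in red. miR-21a-5p lies at 1.76 and 1.57 and miR-431-5p at 1.69 and 1.93, and r over all points is 0.266.

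No miRNA passed in the interaction with limma, while 52 had an unadjusted p under 0.05, edgeR called 1, or 0 without C57BL/6 injured library 1, and DESeq2 9. The 5 with the lowest p, none passing (adjusted p = 0.529), were miR-5114 (2.04), miR-709 (2.09), miR-1195 (2.17), miR-3102-5p.2-5p (1.21) and miR-379-5p (−1.24). miR-379-5p stood at 1117 ± 346 CPM in naive C57BL/6 and at 2472 ± 128, 2429 ± 348 and 2363 ± 56.5 in C57BL/6 injured, CAST/Ei naive and CAST/Ei injured DRG. The edgeR call was miR-1188-5p (log2 5.70, edgeR adjusted p = 0.0455), which had 0 reads in naive CAST/Ei, and DESeq2 also called it, with miR-6240, miR-6538, miR-5114, miR-702-3p, miR-709, miR-3102-5p.2-5p, miR-425-3p and miR-1249-3p. These miRNAs were chosen after their values were seen, apart from those named by the rule. None of the 22 lists was called (camera adjusted p 0.256 to 0.971). Leukocyte miRNAs had a median of 0.43 and the Sfmbt2 cluster one of −0.48 (both adjusted p = 0.256). The count was 0 in every run with 1 replicate left out. The median interaction of all miRNAs, −0.20, moved to −0.07 under quantile normalization, −0.04 with the 3 most abundant miRNAs left out and −0.02 under median-of-ratios scaling.

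Averaged over the strains, 27 miRNAs passed, 20 higher and 7 lower, against 101 at unadjusted p under 0.05 (limma). miR-6540-5p rose by 1.73 ± 0.18 (log2, SE, adjusted p = 5.73e-05), miR-431-5p by 1.81 ± 0.20 (6.52e-05) and miR-21a-5p by 1.67 ± 0.21 (2.28e-04). miR-21a-3p rose by 2.15, miR-7689-3p by 2.05, miR-344e-3p by 2.02, miR-6540-3p by 1.87, miR-344h-3p by 1.61, miR-1197-3p by 1.34 and miR-344d-3p by 1.28. Among the decreases, miR-551b-3p went from 828 ± 246 to 479 ± 16.1 CPM in C57BL/6 and from 861 ± 120 to 452 ± 86.9 in CAST/Ei (log2 −0.83 ± 0.20, adjusted p = 0.0232), with its other arm miR-551b-5p at −1.03. miR-34a-3p changed by −0.78, miR-133a-3p by −0.81, miR-1224-5p by −1.04 and miR-490-3p by −0.93. The 10 named increases passed in every alternative that tested them. Among the decreases miR-1224-5p missed the threshold in 14 of 27 alternatives, miR-490-3p in 13 of 26, miR-551b-3p in 7 of 27 (highest adjusted p 0.174), miR-344b-3p in 7 of 27, miR-133a-3p in 5 of 27, and miR-551b-5p and miR-34a-3p in 1 each. miR-344b-3p fell by 0.73, against the direction of miR-344d-3p, miR-344e-3p and miR-344h-3p from the same locus. miR-344-3p (0.45) and miR-344c-3p (0.58) did not pass.

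Of the miRNAs reported up after nerve injury, 4 of 13 rose over both strains and 0 fell, or 7 and 0 adjusted over the list alone. They were miR-431-5p, miR-21a-5p, miR-21a-3p and miR-511-3p (1.23), and the median was 0.60 (camera adjusted p = 1.12e-05, and adjusted p = 0.00861 with an estimated correlation). In the Dlk1-Dio3 cluster 8 of 88 rose and 0 fell, or 13 and 0 adjusted over the list alone, among them miR-1197-3p, miR-154-3p (0.87) and miR-493-5p (0.84). Its median was 0.30 (camera adjusted p = 2.49e-08, and adjusted p = 0.017 with an estimated correlation). With that correlation and without C57BL/6 naive libraries 4 and 5 it just missed the threshold (adjusted p = 0.05003). Of the skeletal muscle miRNAs 1 of 10 fell, miR-133a-3p, or 4 adjusted over the list alone, which added miR-133b-3p (−0.76), miR-206-3p (−0.89) and miR-1a-1-5p (−0.94). Their median was −0.57 (camera adjusted p = 0.00173, and adjusted p = 0.346 with an estimated correlation, or 0.0328 when C57BL/6 naive libraries 4 and 5 were also left out). The Sfmbt2 cluster had 0 of 47 past the threshold and a median of 0.23 (camera adjusted p = 0.0152, and adjusted p = 0.591 with an estimated correlation), and was not called without C57BL/6 naive libraries 4 and 5 (adjusted p = 0.0646, range over 8 alternatives 0.0246 to 0.682). Among the 18 lists not called (0.0647 to 0.985), 2 of 11 leukocyte miRNAs rose, miR-511-3p and miR-142-5p (0.66), or 3 adjusted over the list alone, and 1 of 8 members of the miR-34 family fell, miR-34a-3p. The medians of the reported-down, neuronal, glia, mural cell, let-7 and Hox lists changed sign under at least 1 other scaling.

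For the averaged effect edgeR gave 17 higher and 9 lower and DESeq2 27 and 21. With the 3 most abundant miRNAs left out of the total the split was 24 and 1, and the median of all miRNAs moved from 0.01 to 0.15. The count was 15 without C57BL/6 injured library 1, 17 without CAST/Ei naive library 1 and 16 without CAST/Ei injured library 3. Without C57BL/6 naive libraries 4 and 5 it was 55 and held all 27.

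In naive DRG 71 miRNAs differed between the strains, 38 higher and 33 lower in CAST/Ei. miR-211-5p, from an intron of the melanocyte gene Trpm1 (chromosome 7, 64205806 to 64205911), was 10.7-fold higher, with 204 ± 94.0 CPM (SD, n = 3) against 18.2 ± 8.45 in C57BL/6 (n = 5; log2 3.42 ± 0.45 SE, adjusted p = 8.12e-05). miR-547-3p and miR-201-5p, neighbours on chromosome X, were also higher, at 48.0 ± 5.31 against 7.24 ± 2.68 CPM (log2 2.64 ± 0.32, adjusted p = 2.99e-05) and at 8.99 ± 3.03 against 0.797 ± 0.645 CPM (log2 2.50 ± 0.35, adjusted p = 1.71e-04). The largest decrease in CAST/Ei on the scale of log2(CPM + 1) was that of miR-341-3p, from an intron of Rian in the Dlk1-Dio3 domain (chromosome 12, 109611500 to 109611595), at 1.63 ± 0.710 against 106 ± 85.5 CPM (log2 −4.89 ± 0.58, adjusted p = 2.99e-05). miR-3065-3p, opposite an intron of Aatk (chromosome 11, 120014767 to 120014853), stood at 35.2 ± 18.9 against 256 ± 68.7 CPM (log2 −2.91 ± 0.31, adjusted p = 1.03e-05).

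The other large increases in naive CAST/Ei were miR-449a-5p (log2 2.42), at 115 ± 34.0 against 25.4 ± 13.4 CPM, miR-376b-5p (2.10), miR-190b-5p (2.08), miR-669f-5p (1.98), miR-669e-5p (1.91), miR-669b-5p (1.67) and miR-322-5p (1.43). Several decreases ran close to absence. miR-467c-5p stood at 0.230 ± 0.307 against 26.9 ± 8.22 CPM (−4.48) and miR-8114 at 0.386 ± 0.244 against 20.6 ± 10.4 CPM (−3.84). miR-3060-3p had 2 reads in naive CAST/Ei against 987 in naive C57BL/6, a depth-scaled ratio of 376 (95% interval 104 to 3105), and miR-3095-3p 3 against 275, a ratio of 69.7 (23.6 to 340.3). miR-7688-5p and miR-1188-5p had 0 reads in naive CAST/Ei against 465 and 305, so they were at least 118-fold and 77.4-fold lower by the floor of 3 reads over the group. miR-7044-3p (−2.78) and miR-1982-3p (−2.42) complete the 10. All 10 decreases passed in every alternative that tested them, as did miR-211-5p, miR-547-3p, miR-201-5p, miR-376b-5p, miR-190b-5p and miR-669e-5p among the increases. miR-669b-5p missed the threshold in 8 alternatives, miR-322-5p in 3 and miR-449a-5p and miR-669f-5p in 2.

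**Figure D4:**
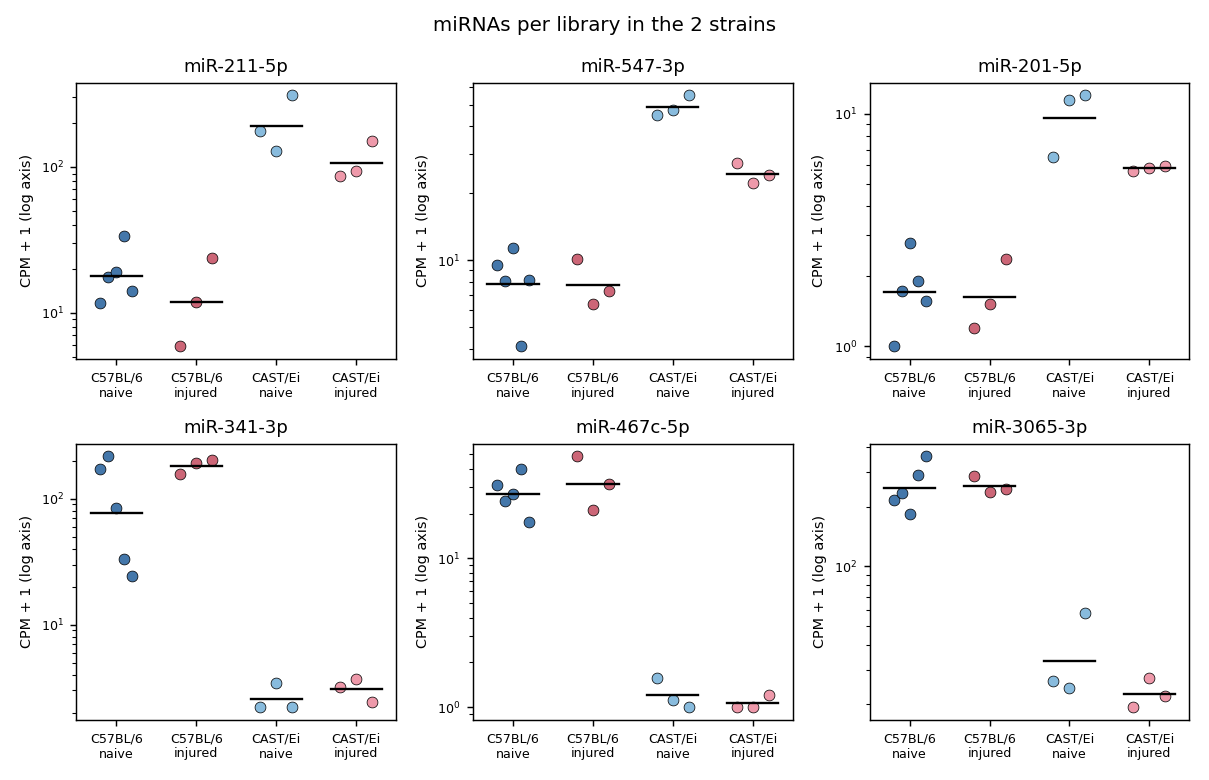
CPM + 1 on a log axis of miR-211-5p, miR-547-3p, miR-201-5p, miR-341-3p, miR-467c-5p and miR-3065-3p in the 4 groups, with 1 point per library and a line at the mean of log2(CPM + 1). miR-341-3p lies at 23.3 to 216 CPM in naive C57BL/6 and at 1.20 to 2.45 in naive CAST/Ei libraries.

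All 3 kept members of the X-linked testis cluster, miR-547-3p, miR-201-5p and miR-201-3p (1.38), were higher in naive CAST/Ei DRG, also adjusted over the list alone, with a median of 2.50 (camera adjusted p = 0.00125, and adjusted p = 0.0477 with an estimated correlation). With that correlation and without C57BL/6 naive libraries 4 and 5 the call was lost (adjusted p = 0.102). These 3 members are miR-547-3p and both arms of miR-201, so they do not stand for the whole cluster. In naive C57BL/6 the mean of miR-201-5p lay below the filter of 5 CPM. It could pass the filter only through other groups, which favours a higher level in CAST/Ei before any test. The Sfmbt2 cluster went both ways, with 9 of 47 higher and 2 lower, or 13 and 5 adjusted over the list alone. miR-669e-5p, miR-669f-5p and miR-669o-5p (1.33) were higher and miR-467c-5p lower (camera adjusted p = 0.448). The Dlk1-Dio3 cluster did as well, with 5 of 88 higher and 4 lower, also adjusted over the list alone. Among them miR-376b-5p, miR-379-5p (1.18) and miR-136-3p (1.36) were higher and miR-673-5p (−1.59) lower (camera adjusted p = 0.385). Neither these counts nor the camera test include miR-341-3p (−4.89), which lies in the same domain but is not on the list. Of 8 Hox cluster miRNAs 2 were higher, miR-10b-5p (0.97) and miR-10b-3p (1.01), and 2 also adjusted over the list alone (camera adjusted p = 0.229). Their level follows the position of a ganglion along the body axis.

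Of 7 myelinating glia miRNAs only miR-211-5p was higher in naive CAST/Ei, or 2 adjusted over the list alone. Of 4 endothelial miRNAs only miR-126b-5p was higher (0.86), or 4 adjusted over the list alone, and of the miR-34 family only miR-449a-5p, or 2 adjusted over the list alone. miR-150-5p was the only lower leukocyte miRNA (−3.06), or 2 were lower adjusted over the list alone. It varied among the C57BL/6 naive libraries, at 417, 1658, 170, 2713 and 2382 CPM in libraries 1 to 5. The only lower neuronal miRNA was miR-7b-5p (−1.01), or none adjusted over the list alone. In the miR-17 and paralogous clusters miR-363-3p was higher (0.89) and miR-92a-3p lower (−1.26), and miR-210-5p was lower (−1.71), with miR-210-3p (−1.63) lower as well adjusted over the list alone. None of the reported-up, reported-down and muscle lists had a member past the threshold, and the reported-up median changed sign under median-of-ratios scaling. For the 21 lists not called, camera adjusted p ran from 0.108 to 0.795.

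Of the 71 calls in naive DRG (limma, 203 at unadjusted p under 0.05), 57 had groups that did not overlap, as had 105 of the 638 miRNAs (16.5%), where chance gives 3.57%. The split of 38 higher and 33 lower depended on the scaling. It was 33 and 38 under quantile normalization, 27 and 44 under median-of-ratios scaling, where the median of all miRNAs moved from 0.12 to −0.02, and 19 and 39 with the 3 most abundant miRNAs left out. edgeR gave 30 and 47 and DESeq2 36 and 82. With the replicate number as a block the count was 111, with 70 higher and 41 lower, of which 64 were among the 71. It was 148 without C57BL/6 naive library 3, and 35, 45 and 33 without CAST/Ei naive library 1, 2 or 3. Without C57BL/6 naive libraries 4 and 5 it was 91, of which 55 were among the 71.

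In injured DRG 21 miRNAs differed between the strains, 5 higher and 16 lower in CAST/Ei. miR-211-5p was 9.02-fold higher, at 109 ± 35.9 against 12.8 ± 9.10 CPM (SD, n = 3 each; log2 3.17 ± 0.50 SE, adjusted p = 7.19e-04). miR-449c-5p stood at 20.0 ± 4.05 against 4.74 ± 1.35 CPM (log2 1.88), and miR-547-3p at 23.6 ± 2.62 against 6.93 ± 1.99 CPM (log2 1.66). miR-201-5p (1.84) and miR-201-3p (1.26) were the remaining increases. miR-341-3p stood at 2.11 ± 0.661 against 183.1 ± 23.1 CPM (log2 −5.90 ± 0.65, adjusted p = 1.62e-05) and miR-3065-3p at 21.8 ± 3.99 against 254 ± 26.1 CPM (log2 −3.49 ± 0.35, adjusted p = 6.09e-06). miR-511-3p, which rose after injury in C57BL/6, was lower in CAST/Ei, at 81.5 ± 9.50 against 203 ± 15.6 CPM (log2 −1.31, adjusted p = 0.0167).

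The other large decreases in injured CAST/Ei were miR-3060-3p (log2 −4.14), miR-8114 (−3.32), miR-1188-5p (−2.98), at 1.46 ± 0.524 against 18.7 ± 5.25 CPM, and miR-3061-5p (−2.48). Reads again came close to 0. miR-467c-5p had 3 against 1007, a ratio of 349 (95% interval 119 to 1697), miR-3095-3p 3 against 180, a ratio of 62.5 (21.03 to 306), and miR-1982-3p 2 against 142, a ratio of 73.9 (20.1 to 616). miR-7688-5p had 0 against 400 reads and was at least 139-fold lower. The 10 named decreases and miR-211-5p passed in every alternative that tested them, while miR-449c-5p missed the threshold in 7, miR-201-3p in 6, and miR-201-5p and miR-547-3p in 4. All 3 kept X-linked testis miRNAs were higher, also adjusted over the list alone, with a median of 1.66 (camera adjusted p = 9.16e-06, and adjusted p = 0.00928 with an estimated correlation). The limits given for this list in naive DRG hold here too. Of the Sfmbt2 cluster 4 of 47 were lower and 0 higher, or 4 and 2 adjusted over the list alone. They were miR-467c-5p, miR-466c-5p (−1.94), miR-466k (−1.88) and miR-669l-5p (−1.71), with camera adjusted p = 0.673. The Dlk1-Dio3 cluster had 1 of 88 listed members lower, miR-673-5p (−1.81, camera adjusted p = 0.921). Again miR-341-3p (−5.90), from the same domain, is not on that list and is not counted. For myelinating glia, with miR-211-5p alone past the threshold, the median was −0.20, the mean 0.34 and camera pointed upward (adjusted p = 0.547). The 21 lists not called had camera adjusted p of 0.213 to 0.938, and the medians of the reported-down, glia, miR-30, Dlk1-Dio3 and Sfmbt2 lists changed sign under at least 1 other scaling.

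All 21 calls in injured DRG (limma, 56 at unadjusted p under 0.05) had groups that did not overlap, as had 229 of the 638 miRNAs (35.9%), where chance gives 10.0%. edgeR gave 5 higher and 16 lower and DESeq2 9 and 16. Modelling only the groups compared gave 105 calls in injured and 21 in naive DRG, and array quality weights gave 109 and 75. The counts of the main model therefore do not show that the strains differ less after injury. Leaving out 1 library gave 15 to 25 calls, and without C57BL/6 naive libraries 4 and 5 there were 36, which held all 21. With the 3 most abundant miRNAs left out the median of all miRNAs moved from −0.06 to 0.05. Most strain differences kept their sign across injury states, though far fewer passed in both. In the main model all 21 calls in injured DRG had the same sign in naive DRG, as had 61 of the 71 naive calls in injured DRG, and 17 passed in both. Across miRNAs, strain in naive DRG and injury in C57BL/6 had r = 0.524, rho = 0.602 and a covariance of 0.330. Both subtract the C57BL/6 naive libraries, and unchanged groups gave r = 0.376 (95% of values from 0.265 to 0.475) and a covariance of 0.0608 in simulation, 0.269 less than observed. With these controls split between the contrasts, the mean over 20 splits was r = 0.284 (0.0613 to 0.419) with a covariance of 0.203. Without C57BL/6 naive libraries 4 and 5, r was 0.331, below the 0.5004 of unchanged groups with 3 controls (0.4195 to 0.5785), and the covariance of 0.138 exceeded the simulated 0.0529 by 0.0854. All these simulations drew each miRNA independently, so their ranges are too narrow. They also gave all groups a common spread, while libraries 4 and 5 of the shared C57BL/6 naive group stood apart (array weights 0.149 and 0.145). A noisier shared group raises the covariance of unchanged groups above the simulated values. The excess over them is therefore not read as a change common to strain and injury. With same-numbered libraries simulated as correlated, unchanged groups gave r = 0.539 (0.456 to 0.619), which the observed 0.524 over all libraries does not exceed.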

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

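All tests of explanations in this part were chosen after the results they bear on had been seen. In the 5 C57BL/6 naive libraries, the only group large enough for the check, 9 of 85 values lay so far from the other 4 that the gap to the nearest exceeded 0.71 of the group's range. Chance gives about 1 in 20.

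Some of these values belong to miRNAs called after injury. miR-344e-3p was at 1.77 CPM in naive library 3 and at 0 to 0.0810 in the others, against a mean of 7.94 CPM after injury. miR-344d-3p was at 60.9 CPM in naive library 5 against 25.5 to 31.4, and miR-133a-3p at 1250 CPM in naive library 1 against 1798 to 2046. Library 5 also held 66.2 CPM of miR-124-5p against 25.3 to 33.3, 429 CPM of miR-142-5p against 302 to 334, and 3.20 CPM of miR-449a-5p against 23.6 to 38.1. Library 4 held 525 CPM of miR-1b-5p against 1359 to 1785 and 6432 CPM of miR-29a-3p against 23472 to 37017. Library 3, the shallowest, held 1.01 CPM of miR-30b-3p against 3.76 to 4.94. Libraries 4 and 5 hold 6 of the 9 values.

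In C57BL/6 naive libraries 4 and 5, 16 miRNAs lay above each of the other 12 libraries, and in library 4 at 10 times or more their median, taking 24.5% and 9.26% of the reads against a median of 0.678% elsewhere. They range from miR-218-5p and miR-367-3p to epithelial (miR-141-3p, miR-200a-3p, miR-200b-3p) and liver (miR-122-5p) miRNAs. More transcription of the hairpins would raise their other arms as well. The other arms had a median log2 excess of 0.501 (95% interval −0.01 to 1.74, 8 arms) where the arms themselves had 4.52. This cannot settle the set, because most members had no other arm to measure. The more abundant other arms rose, for miR-155 (2.17), miR-486 (1.74), miR-3107 (1.71) and miR-494 (0.75). The scarce ones, averaging 1.588 to 4.235 CPM, differed by −0.9347 to 0.2571. In addition, miR-218 was counted through both of its hairpins, and miR-486 and miR-3107 are near-identical copies. For miR-367-3p the explanation is argued against, since miR-302, made from the same cluster, reached at most 1.69 CPM. A candidate explanation is reads from an outside source, which could have entered C57BL/6 injured library 1 as well, where 10 of the 16 members showed an excess within 2-fold of the median share of 2.71% of that in naive library 4 (1.49% to 4.94%). That test leaves the source open, because miR-486-5p, miR-3107-5p, miR-1249-3p, miR-5126, miR-150-5p and miR-448-5p did not follow it. The excess in naive library 5 also ran from 10.1% (miR-155-3p) to 85.6% (miR-150-5p) of that in naive library 4. CAST/Ei naive libraries 1 and 3 were raised in some members too (miR-218-5p at 17984 and 11409 CPM against 3479 in library 2). In CAST/Ei naive library 1 the share was 5.68% for miR-218-5p and 5.43% for miR-367-3p, near the 4.67% and 4.94% of C57BL/6 injured library 1. It was −0.33% for miR-200b-3p and 0.45% for miR-222-3p, against 2.68% and 1.90%. No other biological explanation was tested.

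The miRNAs at least 4-fold lower in CAST/Ei in both naive and injured DRG were 9 in number: miR-341-3p, miR-467c-5p, miR-1188-5p, miR-1982-3p, miR-3060-3p, miR-3065-3p, miR-3095-3p, miR-7688-5p and miR-8114. A CAST/Ei variant in the mature arm could keep reads from aligning to the reference name, and strain-specific transcription is the biological alternative given by the design. They cannot be told apart for the set, because only 1 member, miR-3065-3p, has another arm abundant enough to judge. For that member miR-3065-5p was not lower in naive CAST/Ei (2699 against 1647 CPM, log2 change 0.871, 95% interval 0.13 to 1.61, limma adjusted p = 0.0972). This argues against less transcription of the hairpin only if the reads of miR-3065-5p come from that hairpin. Whether reads of the opposite strand were counted under this name was not tested. A variant or a change in processing of the 3-prime arm stays open.

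Skeletal muscle miRNAs had a median log2 change of −0.57 after injury averaged over the strains (camera adjusted p = 0.00173, and adjusted p = 0.346 with an estimated correlation, or 0.0328 without C57BL/6 naive libraries 4 and 5), but miR-133a-3p alone of 10 passed and 2 lay above 0. Less muscle tissue carried into the injured samples would lower all of them alike. The 95% intervals of 8 of 10 members held that median, but those of 6 of 10 held 0, so the test is too coarse to decide and this explanation stays open. The exceptions, miR-499-5p (0.13) and miR-1b-3p (0.22), lie at 9.29 and 3.84 CPM, and the most abundant member, miR-1a-3p at 8363 CPM, had a change of −0.32 (−0.88 to 0.25). A change of these miRNAs within the ganglia stays open as well and was not tested.

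Chance as the source of the counts was tested by splitting the same libraries in other ways. For the injury effect averaged over strains, the real split called 27 and the highest of the other splits 12, so that 1 of 100 splits, the real one, gave as many. That is the smallest share 100 splits can give, and it argues against chance without excluding it. These splits took no account of replicate numbers, although same-numbered C57BL/6 injured and CAST/Ei naive libraries had correlated deviations. By this test chance is not excluded for the C57BL/6 injury effect (20 calls, highest other 152, with 4 of 56 splits giving as many) nor for strain in naive DRG (71 calls, highest other 152, with 3 of 56 giving as many). In comparisons that share no library with these, 19 of the 20 had the same sign for injury in CAST/Ei. For strain in injured DRG 61 of the 71 did, and 17 passed there. These values argue against chance as the source of all these calls, although miRNAs are not independent replicates. Of the 8 splits of the naive libraries that part all 3 same-numbered pairs, only the real one gave as many as 71, and the highest other gave 7. The other splits with as many therefore left at least 1 pair together, but these 8 also all keep C57BL/6 naive libraries 4 and 5 in the larger group, so pairing and those libraries cannot be told apart here. For C57BL/6 injury and for strain in naive DRG, the splits with many more calls point to a structure of the samples. In each the highest set C57BL/6 naive libraries 1, 4 and 5 together. The splits were too few for a share under 0.05 in CAST/Ei injury (7 calls, highest other 0, 1 of 10) and strain in injured DRG (21 calls, highest other 0, 1 of 10). The interaction could not be tested in this way, because with a real count of 0 (highest other 14) all 100 splits give as many by construction.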

How the results depend on the processing

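No named miRNA that passed and no called list changed direction under any alternative, while 25 of the 134 named results changed sign under at least 1, none of them past the threshold there or in the main model. Medians of lists that were not called did under other scalings, as for neuronal miRNAs after C57BL/6 injury (−0.07, and 0.05 under quantile normalization), and so did the balance of higher and lower calls for strain in naive DRG. Of 134 named results, all kept their side of the threshold with a pseudocount of 0.5, 133 with median-of-ratios scaling, 132 with edgeR, 131 with quantile normalization and 122 with the 3 most abundant miRNAs left out, where 12 were lost. DESeq2 kept 127 and gained 7. Modelling only the groups compared lost 16 of 94. Leaving out 1 library lost 17, 16 and 15 without C57BL/6 injured library 1, 2 or 3, 13, 13 and 16 without CAST/Ei injured library 1, 2 or 3, 16 without CAST/Ei naive library 1, and 0 to 7 without any other. Of the runs chosen after seeing the data, 2 were lost without C57BL/6 naive libraries 4 and 5 and 19 with edgeR without C57BL/6 injured library 1, which leaves fewer samples.

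The C57BL/6 injury count of 20 became 3 when only the groups compared were modelled, 67 with array quality weights, 32 with edgeR, 79 with DESeq2 and 5 with edgeR without C57BL/6 injured library 1. The CAST/Ei injury count of 7 became 3 with a filter of 50 CPM, where fewer miRNAs are tested, 32 with weights, 16 with DESeq2 and 17 without C57BL/6 naive libraries 4 and 5. The naive strain count of 71 became 24 with the filter of 50 CPM, 21 with only the groups compared and 118 with DESeq2. The injured strain count of 21 became 5 with that filter, 105 with only the groups compared, 109 with weights and 36 without C57BL/6 naive libraries 4 and 5. The interaction count of 0 became 1 with edgeR and 9 with DESeq2, and was 0 with edgeR without C57BL/6 injured library 1. The averaged count of 27 became 16 with the filter of 50 CPM, 78 with weights, 48 with DESeq2, 55 without C57BL/6 naive libraries 4 and 5 and 17 with edgeR without C57BL/6 injured library 1. The weights gave C57BL/6 naive libraries 4 and 5 only 0.149 and 0.145. The cause of these changes was not tested.

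Leaving out each replicate in turn gave 6 to 70 calls for C57BL/6 injury, 3 to 10 for CAST/Ei injury, 33 to 148 for strain in naive DRG, 15 to 25 for strain in injured DRG, 0 to 0 for the interaction and 15 to 34 for the averaged effect. The highest counts for C57BL/6 injury and naive strain came without C57BL/6 naive library 3. The correlation of the strains' injury fold changes ran from 0.222 to 0.309, and that of strain with injury from 0.426 to 0.626. The value for unchanged groups moves with the number of shared controls, from 0.374 with all 5 to 0.427 to 0.429 with 1 left out and 0.5004 without C57BL/6 naive libraries 4 and 5, where r was 0.331. Without library 4 alone r was 0.426 and without library 5 alone 0.441, both within the simulated ranges (0.335 to 0.513 and 0.326 to 0.527).

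Of the 16 calls of lists (11 higher, 5 lower), 5 held with an estimated correlation and 8 with fry, for its directional and for its mixed test alike. With quantile normalization 15 held, with the replicate number as a block 13, and with a filter of 50 CPM 10, which left 13 to test again. Without C57BL/6 naive libraries 4 and 5, 14 held, or 6 with an estimated correlation. The run without those libraries lost the Sfmbt2 cluster in C57BL/6 and in the average, and gained 1 call. The cause was not tested.

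The labels number the replicates of each group, and it is not established that the numbers pair the libraries. All 3 same-numbered pairs of naive C57BL/6 and CAST/Ei libraries had correlated deviations above 0.1, but 1 of 3 did for injury in C57BL/6, 1 of 3 for injury in CAST/Ei and 0 of 3 for strain in injured DRG. All 3 also did between C57BL/6 injured and CAST/Ei naive libraries (up to 0.555), groups that both enter the interaction, the averaged effect and the correlations of fold changes. With same-numbered libraries simulated at these correlations, unchanged groups gave r = −0.195 (−0.305 to −0.084) for injury in the strains, against 0.266 observed. For strain with injury they gave 0.539 (0.456 to 0.619), which the observed 0.524 does not exceed. The simulations with libraries left out or correlated were added after seeing the data. They too drew each miRNA independently and gave all groups a common spread. Of 18 same-numbered pairs 10 were above 0.1 (range −0.194 to 0.555), and 4 of 12 libraries correlated best with their own number. Differently numbered libraries reached 0.291 (C57BL/6 injured library 3 with CAST/Ei naive library 2). With the replicate number as a block the counts were 37 for C57BL/6 injury, 21 for CAST/Ei injury, 111 for strain in naive DRG, 36 for strain in injured DRG and 59 for the averaged effect, and the correlation of strain with injury was 0.331. Numbers 4 and 5 occur only in C57BL/6 naive, so the block also sets those libraries aside. For strain in naive DRG it ended no named call and no call of a list.

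Depth limits the scarce miRNAs. One read is worth up to 0.253 CPM, and miR-344e-3p, miR-201-5p and miR-21a-3p lie within a few reads of 0 in some groups.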

Other observations

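All tests in this part were chosen after the results had been seen. Both arms of a hairpin tended to move together in every contrast. For miR-21a, miR-6540 and miR-551b both arms passed in the averaged effect, in the same direction, at 1.67 and 2.15, 1.73 and 1.87, and −1.03 and −0.83 on the log2 scale. For 199 hairpins with both arms kept, the averaged log2 changes of the arms had a Pearson correlation of 0.546 (permutation p = 1e-05, the smallest that 100000 permutations can give). In the other contrasts it ran from 0.411 for the interaction, where no miRNA passed, to 0.586 for injury in CAST/Ei, so it is not a mark of the injury response. It is consistent with changes in the amount of the hairpin, and arms of near-identical copies may add to it, since hairpins are not independent replicates.

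Neighbouring hairpins also moved together, again not only with injury. With the listed members of the Dlk1-Dio3 and Sfmbt2 clusters left out, 57 pairs of hairpins lay within 10 kb of each other. Their correlation in the averaged injury change was 0.653 (permutation p = 1e-05, again the smallest possible), as joint transcription of genomic clusters could give. In the other contrasts it ran from 0.252 for the interaction to 0.858 for strain in injured DRG. The miR-344 copies on chromosome 7 are an exception within 1 locus, since miR-344e-3p, miR-344h-3p and miR-344d-3p rose by 2.02, 1.61 and 1.28 while miR-344b-3p fell by 0.73. The CPM of miR-344b-3p went from 49.6 to 36.2 in C57BL/6 and from 98.2 to 47.9 in CAST/Ei. Reads shared between near-identical copies were not tested as a source of this.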
